A study of Mus musculus with 18 samples.

How the data were processed

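RNA from 18 samples was measured on Affymetrix Mouse Gene 2.0 ST arrays: hypothalamus, pituitary and ovary of control and transported mice, each in a high, a low and a pool sample by number of ovulated oocytes. Per the labels, RNA was extracted with Trizol and labelled with biotin from 6 ug of total RNA. The deposited table holds log2 signals, a single processed value for each transcript cluster and array, which the authors made with Transcriptome Analysis Console. Its version, background correction, normalization and filters are not stated. The log base was read from the values: the highest, 13.66, lies above the natural logarithm of the largest 16-bit scanner reading (11.09) and below its log2 value (16). No value was missing (0), and among 153 pairs of arrays 0 were identical.

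The table has 41345 transcript clusters, of which 25335 carry a gene annotation and 16010 do not. Clusters naming exactly 1 gene (23521) were kept for the gene tests, and the 1814 naming several genes were left out. Where a gene had more than 1 cluster (1082 genes), the cluster with the highest mean over all arrays was used, which gave 22180 genes. Entrez identifiers of 23328 clusters matched the gene table of assembly GRCm38.p6, which changed 0 symbols and was used for names, gene type and the length of the genomic span. The assembly behind the array annotation is not named in the sources used here, so no coordinates are given. No filter on low values was applied.

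Each tissue was tested by itself. Stress was compared with control in limma 3.58.1 under R 4.3.3 (lmFit and eBayes on 6 arrays, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. High was compared with low ovulation in a model with class and treatment. Differences of the stress effect between tissues were tested as interactions on all 18 arrays with the animal as a block, since the tissues of a treatment and class come from the same mouse or pool. All p values are two-sided. Intervals are 95% confidence intervals from limma. The median standard error of a stress difference was 0.23 in hypothalamus, 0.27 in pituitary and 0.21 in ovary. Both the number of arrays and the class differences left in the residual limit this precision. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

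The lists of pathways and cell types (39 in all), the tests, the rule for naming genes and most alternatives were fixed before the data were examined. Lists with at least 5 measured genes were tested with limma camera at its preset correlation of 0.01, with adjustment over the lists of a tissue (25, 26 and 25 in hypothalamus, pituitary and ovary). The rule named up to 12 genes in each direction per tissue among those that passed with no overlap between groups. Open places were filled with the genes of smallest unadjusted p that showed no overlap and lay at or above the median level. It added a fixed set of reproductive and stress genes and up to 4 members of each described list. For high against low it took up to 5 genes per direction, and for differences between tissues the 5 genes of smallest adjusted p, with ties broken by unadjusted p. Genes with only predicted or clone names, small RNAs, odorant receptors and antigen receptor segments, recognized by their symbols, were counted but not named (4950 genes). The small RNAs Rprl2 and Vaultrc5 were missed by these symbol patterns and are named below. Cyp19a1 and Lhcgr had no cluster naming them alone.

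Whether the ovulation class pairs control with stress samples was checked from the deviations of each array from its group mean. The 9 same-class correlations ran from 0.359 to 0.727 and the 18 different-class ones from -0.521 to 0.321, and each of the 9 was highest with its own class. Deviations within a group sum to 0, so the difference of pools from single mice alone would set the pools apart. Among single mice in pituitary, same-class values were 0.366 and 0.359 and different-class ones 0.321 and 0.313, so pairing was weak there. They were 0.373 and 0.374 against 0.190 and 0.263 in ovary, and 0.405 and 0.520 against 0.135 and -0.0502 in hypothalamus. The pairing comes from the class names and not from shared animals. The fit with class as a block is given beside the main one where it changes a count.

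The steps were tested on simulated data with 200 changed genes placed on the residual spread of each tissue. The test of stress without a block recovered 68.2% of 4-fold changes in hypothalamus, 40.9% in pituitary and 84.8% in ovary, and 1.49%, 0% and 0% of 2-fold changes. With the block it recovered 97.0%, 67.2% and 95.5% of 2-fold changes, with 14 false calls among 153, 10 among 125 and 16 among 160. High against low recovered 83.6%, 47.8% and 77.6% of 2-fold changes, with 30 false calls among 161, 19 among 119 and 20 among 142. These shares of false calls lie above the threshold of 0.05. The ovary minus hypothalamus interaction recovered 98.5% of 4-fold and 19.4% of 2-fold changes. Simulated lists shifted by 0.25 were recovered in 100%, 95% and 100% of runs. These lists were random genes simulated without correlation between genes. In the data the estimated correlation was 0.72 for interferon genes in ovary and 0.34 for cell cycle genes in pituitary. The runs therefore do not measure how the test behaves on such lists.

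Alternatives covered the class block, all 18 arrays in a single model, a trended robust prior, array weights, quantile normalization, centring on array medians, a filter at the median level, other ways to reduce clusters to genes, other thresholds, leaving out each array, and for lists fry and an estimated correlation. Leaving out the pool arrays, the estimated correlation together with the block, and the lists for high against low were added after the data had been seen. Genes were called specific to a tissue where its lowest single-mouse array exceeded the highest single-mouse array of the other tissues by more than 3 on the log2 scale, a rule also set after the data had been seen, in place of a looser one tried before it. The excess of such genes in a pool was taken over the mean of the 4 single-mouse arrays of that tissue.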

Results

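RNA of hypothalamus, pituitary and ovary was measured on 18 arrays, 6 for each of the 3 tissues. Female BABL/c mice (strain name as labelled) from 10 littermate pairs were divided between a control group and a stress group. The stress group was driven over 1000 km at about 50 km/h for nearly 10 h, and all mice were superovulated at 9 weeks of age. Within each group, 1 sample of every tissue came from the mouse with the most ovulated oocytes (high), 1 from the mouse with the fewest (low) and 1 from a pool of the other 8 mice. Each tissue therefore had 3 control and 3 stress arrays, and only 2 of the 3 in a group were single mice. The small number of arrays limits the precision of every value.

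Hormone and cell markers placed the arrays in their labelled tissues. All 8 measured hypothalamic markers, among them Pmch (melanin-concentrating hormone) and Hcrt (orexin), were higher in every hypothalamus array than in any array of another tissue. The same held for all 7 measured pituitary markers and for 6 of 7 ovarian markers, with Amh the exception. Arrays of the same tissue correlated at 0.928 to 0.988, and arrays of different tissues at 0.866 to 0.955.

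Several pool arrays also carried transcripts of other tissues. Prl, the prolactin gene of pituitary lactotropes, read 10.82 (log2 signal) in the control ovary pool and 11.44 in the stressed ovary pool, against 3.63 to 5.09 in the 4 single-mouse ovary arrays. Gh read 10.08 and 10.46 in those pools against 5.01 to 5.90. Over 23 genes high in pituitary alone the median excess was smaller, 0.33 in the control and 0.45 in the stressed ovary pool, with 4 genes above 1 in each. Cyp11a1, the enzyme that starts ovarian steroid synthesis, read 11.34 in the stressed pituitary pool, 4.54 in the control pituitary pool and 3.51 to 5.31 in single-mouse pituitaries. In hypothalamus it read 10.52 in the stressed pool, 5.77 in the control pool and 4.10 to 6.99 in single mice. The neuronal gene Calb2 read 8.46 in the stressed pituitary pool, 5.19 in the control pool and 3.39 to 3.74 in single-mouse pituitaries. Over 61 genes high in ovary alone, the median excess over single mice was 1.99 in the stressed and 0.03 in the control pituitary pool, and 1.22 and 0.05 in the hypothalamus pools. Over 93 genes high in hypothalamus alone it was 1.18 in the stressed pituitary pool (88 higher) and 0.70 in the control one (85 higher). The control hypothalamus pool showed no such excess (-0.01 for pituitary genes). Single-mouse arrays varied as well: in hypothalamus Prl ran from 5.53 to 9.26 and Gh from 5.67 to 8.14, highest in the control low mouse and next in the stressed high mouse.

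**Figure D1:**
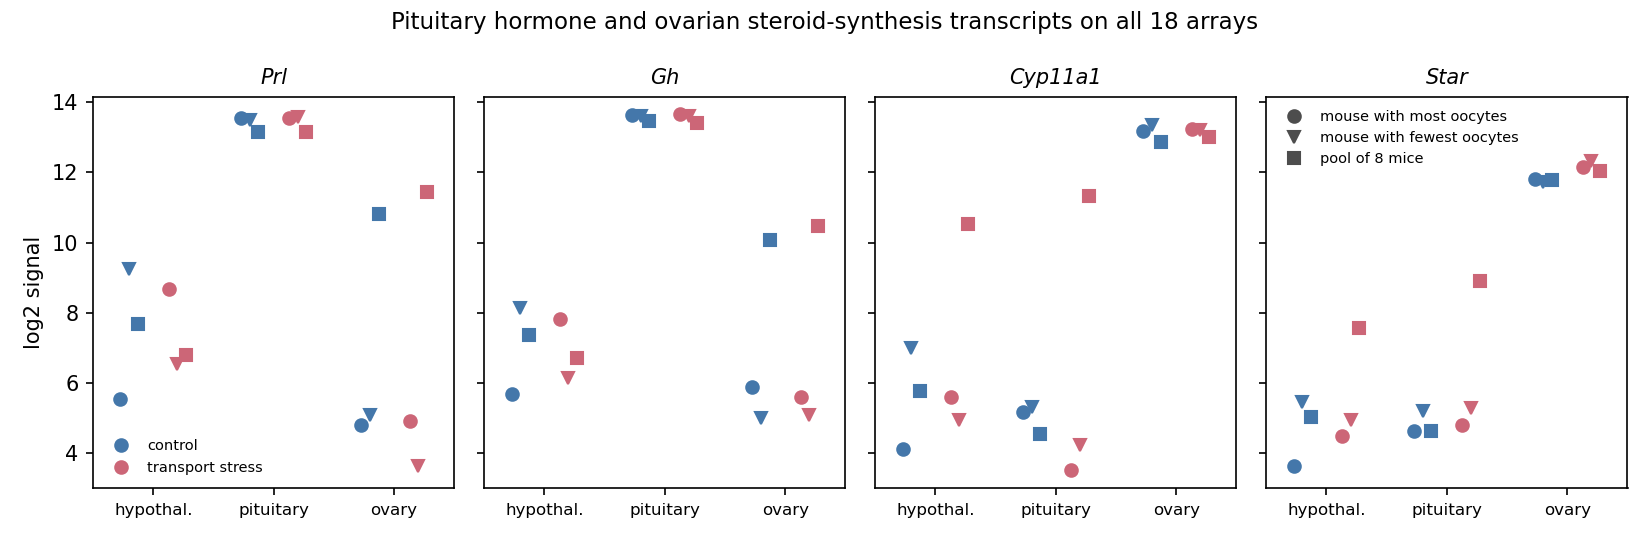
Log2 signal of 2 pituitary hormone genes (Prl, Gh) and 2 ovarian steroid-synthesis genes (Cyp11a1, Star) on all 18 arrays, 1 point per array, by tissue, treatment (colour) and ovulation class (marker). Prl and Gh were near 10 or above in both ovary pools, and Cyp11a1 reached 11.34 in the stressed pituitary pool.

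The main question of the series was which genes transport stress altered along the axis that governs ovulation. In hypothalamus, Col5a1, a fibrillar collagen chain (transcript cluster 17368569), averaged 5.46 ± 0.18 (SD, n = 3) in control and 6.13 ± 0.14 (SD, n = 3) in stressed samples, a difference of 0.66 that was positive in each ovulation class. As for every gene filled in, groups without overlap were required, so that shared sign was fixed by the choice. Aldh1a2, an enzyme of retinoic acid synthesis (cluster 17519112), averaged 6.63 ± 0.39 (SD, n = 3) in control and 5.82 ± 0.34 (SD, n = 3) in stressed samples, a difference of -0.81. Among synaptic genes, Shank3, a postsynaptic scaffold, differed by -0.59 and Lrrtm1, a synaptic adhesion protein, by -0.50. Shank3 differed by -0.86 between the high mice and between the low mice, but by -0.03 between the pools. For Lrrtm1 the values were -0.61, -0.69 and -0.19. Among reproductive and stress peptides, Gnrh1 differed by 0.12, Kiss1 by 0.20, Crh by 0.04, Npvf by -0.07 and Pomc by -0.48 (-1.26 between the low mice, -0.08 in each other class). The control low mouse also had the highest hypothalamic Prl and Gh, and Pomc read 12.64 to 12.97 in pituitary. Kiss1 read 4.66 to 5.52 in hypothalamus and 4.27 to 5.32 in pituitary. Gnrh1 read 4.82 to 5.30, against up to 4.58 in other tissues, so neither Kiss1 nor Gnrh1 could show a change well. None of these genes passed the threshold. The 95% confidence interval ran from -0.33 to 0.57 for Gnrh1 and from -1.37 to 1.22 for Npvf.

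Of 22180 genes, 0 passed at an adjusted p under 0.05 in the limma comparison of hypothalamus, where the lowest adjusted p was 0.99998. At an unadjusted p under 0.05 there were 245 genes (110 higher and 135 lower under stress), against 1109 for independent arrays with no change, and with ovulation class as a block 0 passed and 923 were under that level. The 3 stress arrays lay wholly above or below the 3 control arrays for 1007 genes, or 4.54%, where chance gives 10% if arrays are exchangeable. Arrays of the same class were alike, and the other 3 splits that part each class pair gave 4.44% to 5.20%. The genes named here beyond the hormones were filled in by their unadjusted p and did not pass the threshold. The others with higher values were Wdr63, H2-Ab1, Col4a1, Cd274, Nr5a1, Tnnc1, Hspe1, H2-K1, Cdc42bpg, Odc1 and Itgb3 (0.36 to 0.62). Itgb3 differed by 1.67 between the pools and by 0.04 and 0.15 between the high and the low mice, and it read 9.59 to 10.57 in ovary, whose transcripts the stressed pool held. The others with lower values were Ramp3, Synpo2, Lrtm2, Shox2, Pard6a, Cox6a2, Igfbp2, Tspan33 and Slc31a2 (-0.86 to -0.43). Ramp3, at -0.86, differed by -1.42 and -1.13 between the high and the low mice and by -0.02 between the pools. H2-K1, an antigen-presentation gene induced by interferon, differed by 1.35 between the high mice, by 0.02 between the low mice and by 0.44 between the pools. The first value came from a low reading in the control high mouse (5.622, against 6.795 and 6.57 in the other controls). The stressed samples read 6.973 (high), 6.819 (low) and 7.015 (pool).

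Markers of forebrain regions next to the hypothalamus fell as a group in stressed samples, with 10 of 15 genes lower and a median of -0.29 (limma camera, adjusted p = 0.00444). This was adjusted p = 0.857 with an estimated correlation. The thalamic gene Prkcd differed by -0.94, Tcf7l2 by -0.77, the cortical and thalamic glutamate transporter Slc17a7 by -0.71 and Lef1 by -0.52. These differences came from single mice: Prkcd differed by -1.76 between the high mice, by -1.23 between the low mice and by 0.17 between the pools. Without the control low mouse the list had an adjusted p of 0.128, and without the stressed high mouse 0.534 (range over all alternatives 0.000277 to 0.960).

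With ovulation class as a block, 5 lists passed in hypothalamus in place of 1, and with the block and an estimated correlation 0 did (lowest adjusted p = 0.846 with an estimated correlation). Oligodendrocyte and myelin genes were lower for 13 of 15 (median -0.18, blocked adjusted p = 0.0318; Cldn11 -0.30, Mog -0.25). Endothelial and mural cell genes were lower for 15 of 18 (median -0.13, blocked adjusted p = 0.0437; Vwf -0.30, Flt1 -0.15). Cell cycle genes were higher for 14 of 23 (median 0.08; Top2a 0.55, Mki67 0.45) and ribosomal protein genes for 16 of 21 (median 0.10; Rpl30 0.16, Rpl19 0.14), each at a blocked adjusted p of 0.0437. The cell cycle median was 0.12 between the pools, of which the stressed one held ovarian transcripts. It was 0.03 between the high mice and 0.05 between the low mice, and the list had an adjusted p of 0.442 without the pool arrays. Without the pool arrays, 2 lists passed, the neighbouring forebrain genes and the interferon response genes (adjusted p = 0.0109; 0.13 with all arrays and 0.857 with an estimated correlation). Leaving out 1 array let other lists pass, and only the removals that did so follow. Immediate early genes passed without the stressed low mouse (0.000434) or the control pool (0.0252; adjusted p = 0.907 with all arrays and an estimated correlation). Their median was 0.27 between the high mice, but -0.13 between the low mice and -0.05 between the pools. Interferon genes passed without the stressed low mouse or the control pool (0.00115 and 0.0309), and cell cycle genes without these (0.0192 and 0.0309) or the stressed high mouse (0.0409). The interferon median was 0.54 between the high mice, but -0.07 between the low mice and -0.19 between the pools. Endothelial genes passed without the control high mouse (0.00195) or the stressed pool (0.00121), and ribosomal protein genes without the control high mouse (0.000477). Between the high mice, the low mice and the pools, the endothelial medians were -0.07, -0.14 and -0.06, and the ribosomal ones -0.08, 0.22 and 0.11. The interferon, cell cycle, endothelial and ribosomal lists had adjusted p = 0.857 with all arrays and an estimated correlation. Igtp of the interferon list differed by 1.45 between the high mice and by 0.33 between the low mice.

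Lists of reproductive and stress control did not pass in hypothalamus with all arrays. Genes controlling GnRH secretion were higher for 14 of 21 (median 0.01, adjusted p = 0.536; Th 0.49, Esr2 0.25, Gpr101 -0.31). Without the control pool they passed (adjusted p = 0.0309; adjusted p = 0.857 with all arrays and an estimated correlation), and without the control low mouse or the stressed pool they pointed down (0.735 and 0.956). Stress and feeding peptides were higher for 11 of 22 (median 0.01, adjusted p = 0.885; Sst -0.26, Pmch 0.26). Glucocorticoid-induced genes were higher for 13 of 24 (median 0.01, adjusted p = 0.679; Sgk1 0.29, Angptl4 0.19). Inflammatory genes were higher for 13 of 21 (median 0.09, adjusted p = 0.423), with Ptgs2 at 0.73 and Socs3 at -0.56. Hypothalamic Ptgs2 read 4.15 to 4.49 in control samples, and 4.76, 4.83 and 5.62 in the stressed high, low and pool samples. In ovary, whose transcripts the stressed pool held, Ptgs2 read 6.27 to 9.24. No member of any list passed, over all genes or adjusted over the list alone (0 in each of the 3 tissues; limma). Median, mean and test differed in sign for the stress and feeding peptides, choroid plexus, microglia, heat shock and histone lists.

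In pituitary, none of the hormone genes passed. Fshb averaged 11.79 ± 0.53 (SD, n = 3) in control and 11.77 ± 0.18 (SD, n = 3) in stressed samples, Lhb differed by -0.09, Cga by -0.03, Prl by 0.04, Pomc by -0.18 and Gnrhr, the GnRH receptor, by 0.11. With quantile normalization Fshb and Cga took a positive sign and Prl a value of 0, and with centring Prl took a negative one. Prl read 13.15 to 13.60, near the highest value of the table (13.66), and Lhb 5.68 to 6.20 against up to 5.21 in other tissues, so neither could show a change well. Nr4a1, an immediate early nuclear receptor (cluster 17315178), averaged 9.15 ± 0.07 (SD, n = 3) in control and 9.88 ± 0.48 (SD, n = 3) in stressed samples, a difference of 0.73 (0.47 without the stressed high mouse). Mad2l1, a spindle checkpoint gene (cluster 17459236), averaged 7.43 ± 0.21 (SD, n = 3) and 6.47 ± 0.46 (SD, n = 3), a difference of -0.96. Neat1, a nuclear long noncoding RNA, differed by 1.18, with 2.14 between the pools and 0.67 without the stressed pool. It read 8.17 in the stressed pituitary pool, above the 7.64 of the stressed ovary pool, and 7.64 to 9.10 over the ovary arrays. None of these genes passed the threshold.

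In the limma comparison of pituitary 0 of 22180 genes passed, with a lowest adjusted p of 0.9999. There were 294 genes at an unadjusted p under 0.05 (137 higher and 157 lower), and with the class block 0 genes passed and 1110 were under that level. Groups did not overlap for 1349 genes, or 6.08%, where chance gives 10% for exchangeable arrays and the other 3 splits that part each class pair gave 4.59% to 6.91%. Without the pool arrays 0 genes passed and 1578 were at an unadjusted p under 0.05, and with array weights 0 and 3135. The remaining genes filled in with higher values were Trim43c (1.23), Zfp992, Col2a1, Actn2, Gip, Ccn5, Mical1, Cgn, Naf1 and Slc22a13 (0.51 for the last). Those with lower values were Nqo2 (-0.87), Ecrg4, Nrtn, Gpr6, Zfp764, Ccdc115, Grap, Trpt1, Endog, Gnmt and Clgn (-0.57 for the last), and none passed. Nrtn encodes the growth factor neurturin, Endog a mitochondrial endonuclease and Gnmt glycine N-methyltransferase.

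Proliferation genes fell as a group in stressed pituitary, with 23 of 23 lower and a median of -0.35 (limma camera, adjusted p = 0.000416). The call did not hold with an estimated correlation (adjusted p = 0.852). Ube2c differed by -0.67, the replication helicase subunit Mcm3 by -0.50, cyclin Ccnb2 by -0.47 and the mitotic kinase Aurka by -0.35. The median was -0.70 between the high mice and -0.54 between the low mice, but 0.26 between the pools, where the stressed pool held ovarian transcripts. Replication-dependent histone genes, which can follow RNA quality, were also lower for 6 of 7 (median -0.24, adjusted p = 0.283), with -0.89 between the high mice, -0.03 between the low mice and 0.06 between the pools. The proliferation list lost its call without the control low mouse (adjusted p = 0.159) or without the stressed high mouse (0.168; range over all alternatives 1.65e-10 to 0.922). Genomic span was compared over protein-coding genes at or above the median level. Across 10526 such genes, the stress difference in pituitary rose with genomic span (Spearman rho 0.376 across genes, which are not independent replicates). The rho was 0.325 between the high mice and 0.251 between the low mice, but 0.068 between the pools. In hypothalamus it was -0.098 for the stress difference.

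Immediate early genes rose as a group in stressed pituitary, with 17 of 22 higher and a median of 0.13 (adjusted p = 0.00169). It was adjusted p = 0.852 with an estimated correlation. The neuronal activity gene Npas4 differed by 0.92, Egr1 by 0.82, Nr4a1 by 0.73 and Nr4a3 by 0.33. All 4 were higher under stress in each ovulation class, which their choice by smallest unadjusted p favoured. The median of the list was 0.24 between the high mice, 0.12 between the low mice and -0.02 between the pools. Without the control low mouse the adjusted p was 0.104, and without the stressed high mouse 0.0579 (range over all alternatives 0.000152 to 0.922).

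Interferon-induced genes rose as a group in stressed pituitary, with 16 of 19 higher and a median of 0.36 (adjusted p = 0.000416). Estimating the correlation gave adjusted p = 0.852. The antiviral genes Mx2, Ddx58, Bst2 and Rsad2 differed by 0.82, 0.59, 0.57 and 0.49. The rise sat in a single animal: the median was 1.53 between the high mice, -0.20 between the low mice and -0.07 between the pools. Without the stressed high mouse the list pointed down (adjusted p = 0.114), and without the control pool the adjusted p was 0.0712 (range over all alternatives 7.43e-10 to 0.979).

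Other pituitary lists did not pass. Hormone and receptor genes were lower for 16 of 25 (median -0.03, adjusted p = 0.968; Inhba 0.50, Fst 0.46, Chga -0.23), and gonadotrope genes were higher for 4 of 8 (median 0.04, adjusted p = 0.283). Respiratory chain genes were lower for 13 of 14 (median -0.18, adjusted p = 0.166; Sdhb -0.47, Cox4i1 -0.31). Heat shock genes were lower for 13 of 17 (median -0.12, adjusted p = 0.283; Dnajb1 -0.64, Stip1 -0.36). Glucocorticoid-induced genes were lower for 15 of 24 (median -0.07, adjusted p = 0.968; Pdk4 0.46). Astrocyte genes had a median of 0.81 between the pools and -0.25 between the low mice, and Acsbg1 differed by 3.10 between the pools. Genes high in hypothalamus alone had a larger median excess in the stressed pool (1.18 against 0.70), and the source of this excess stayed open. The astrocyte list passed without the stressed high mouse (adjusted p = 0.00467) or the stressed low mouse (0.0174), both with the stressed pool kept. Its median between the high mice was -0.04, and it had adjusted p = 0.943 with an estimated correlation. Oxidative stress genes passed without the stressed pool (0.0282), where they pointed down, and likewise had adjusted p = 0.943. Without the pool arrays 6 lists passed in place of 3, the added ones being respiratory chain (adjusted p = 0.0164), heat shock (0.0134) and cholesterol synthesis (0.0389) genes, all lower. With all arrays and an estimated correlation these had adjusted p = 0.852, adjusted p = 0.852 and adjusted p = 0.983, and cholesterol synthesis pointed up. Median, mean and test differed in sign for the hormone, adipose, oligodendrocyte, somatotrope, endothelial, lymphocyte, glucocorticoid, apoptosis, circadian and cholesterol lists.

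**Figure D2:**
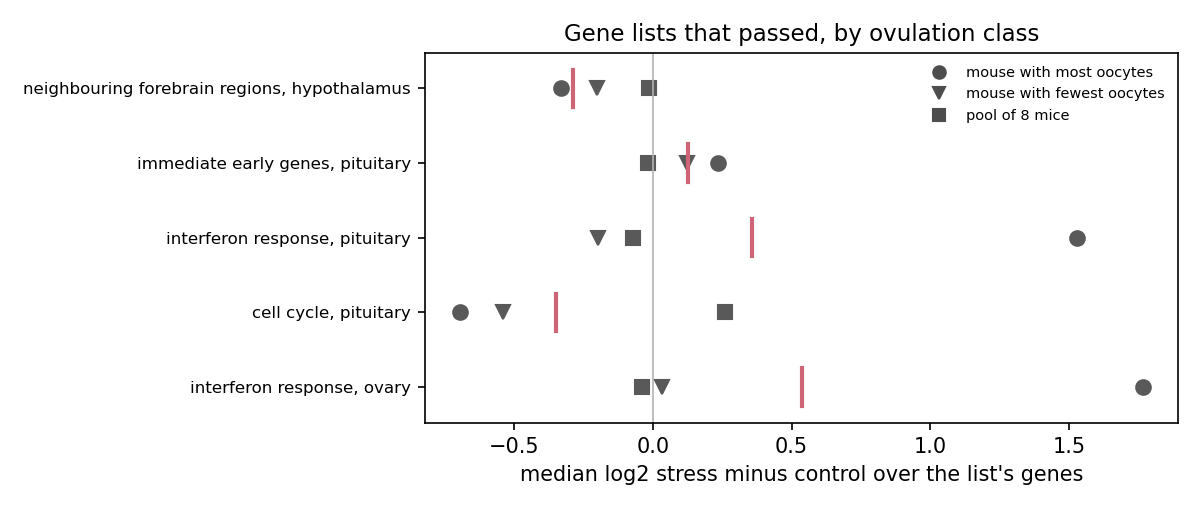
Median log2 difference, stress minus control, over the genes of each list that passed, for the high mice, the low mice and the pools (grey markers) and for all 3 arrays per group (red bar). The interferon medians were 1.53 and 1.77 between the high mice of pituitary and ovary and -0.20 to 0.03 in the other classes.

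In ovary, Star, which brings cholesterol to the steroid-synthesis enzymes (cluster 17500195), averaged 11.77 ± 0.04 (SD, n = 3) in control and 12.17 ± 0.14 (SD, n = 3) in stressed samples, a difference of 0.40 found in each ovulation class. Cyp11a1, the next enzyme of the pathway, differed by 0.03 (-0.02 after quantile normalization), Fshr by 0.02 and Amh by -0.12. Ptgs2, the prostaglandin synthase needed for ovulation, averaged 7.51 ± 1.26 (SD, n = 3) and 8.77 ± 0.50 (SD, n = 3), a difference of 1.26, with 2.56 between the low mice and 0.44 between the pools. The difference was 0.64 without the control low mouse and more than 1.5 times larger without the control pool. Ifi205, an interferon-inducible gene (cluster 17230111), differed by 0.89 between the high mice, 1.08 between the low mice and 1.02 between the pools. Saa2, an acute phase protein gene, differed by -1.06 and S100a4 by -0.83. None of these genes passed the threshold.

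In the limma comparison of ovary 0 of 22180 genes passed, with a lowest adjusted p of 0.999. There were 592 genes at an unadjusted p under 0.05 (344 higher and 248 lower), and with the class block 0 genes passed and 2198 were under that level (lowest adjusted p 0.499). Groups did not overlap for 1946 genes, or 8.77%, where chance gives 10% for exchangeable arrays and the other 3 splits that part each class pair gave 4.64% to 4.86%. The remaining genes filled in with higher values were Ms4a6d (1.05), Casp12, Tug1, Sh3bgrl, Zfp322a, Cd2ap, Wwp1, Kif11, Igsf6, Mios and Zfp961 (0.54 for the last). Those with lower values were Mmel1 (-0.72), Dpysl4, Qpct, Cpxm1, Pf4, Pdlim4, Agap3, Shld1, Tprn and Zfp553 (-0.49 for the last), and none passed. Ms4a6d and Igsf6 are membrane proteins of myeloid cells, Kif11 is a mitotic motor and Pf4 a platelet chemokine.

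Interferon-induced genes rose as a group in stressed ovary, with 19 of 19 higher and a median of 0.54 (limma camera, adjusted p = 4.10e-06). The call was lost with an estimated correlation (adjusted p = 0.844). The GTPases Gbp3, Irgm1 and Igtp differed by 1.20, 0.78 and 0.77, and the RNA sensor Ifih1 by 0.79. As in pituitary, the rise sat in the stressed high mouse: the median was 1.77 between the high mice, 0.03 between the low mice and -0.04 between the pools. Without that mouse the adjusted p was 0.972 (range over all alternatives 9.45e-13 to 0.990). Across 10620 protein-coding genes at or above the median level the stress difference in ovary also rose with genomic span (Spearman rho 0.3499 across genes).

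**Figure D3:**
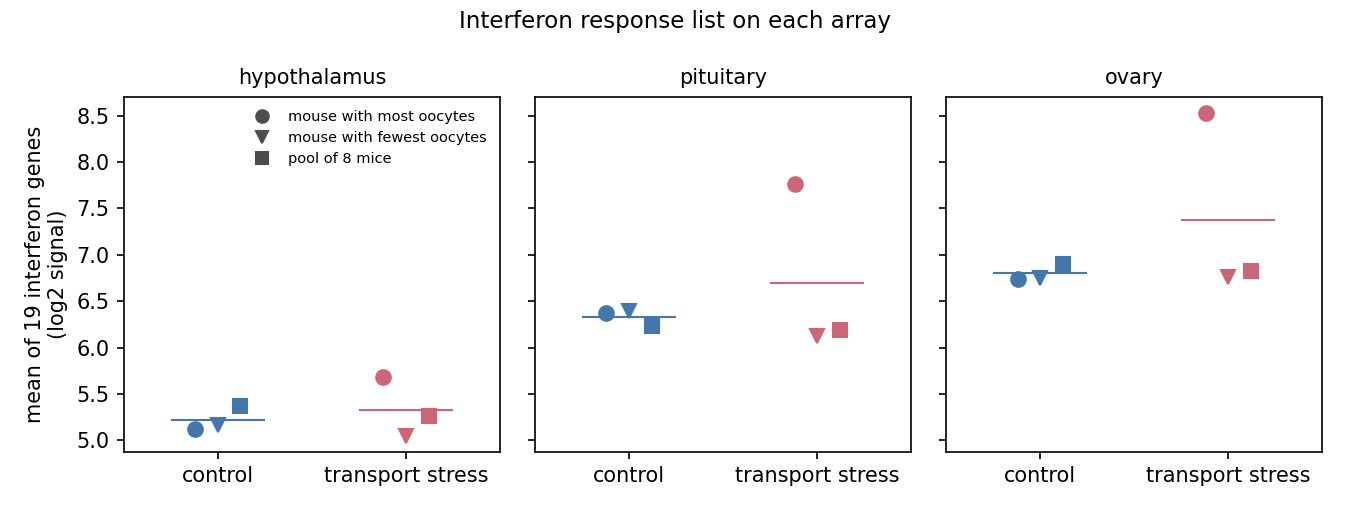
Mean log2 signal of the 19 interferon-induced genes on each array, by tissue, treatment and ovulation class, with group means as lines. The stressed high mouse read 7.76 in pituitary and 8.53 in ovary, above all other arrays of those tissues (6.13 to 6.40 and 6.74 to 6.91).

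With the class block, 3 lists passed in ovary in place of 1, and with the block and an estimated correlation 0 did (lowest adjusted p = 0.966 with an estimated correlation). Granulosa and follicle growth genes were higher for 19 of 22 (median 0.14, adjusted p = 0.0904, blocked 0.0431; Prkar2b 0.62, Bex2 0.47, Ccnd2 0.28). Their median was -0.21 between the high mice and 0.45 between the low mice, and the adjusted p ran from 0.00177 to 0.990 over all alternatives. It was 0.00246 without the stressed high mouse, 0.0169 without the control high mouse and 0.00177 without the control pool. Without the stressed pool it was 0.635, and without the control low mouse the list pointed down (0.958). The adjusted p was 0.962 with an estimated correlation. Replication-dependent histone genes, whose messages lack a poly(A) tail and which can follow RNA quality, were lower for 6 of 7 (median -0.32, adjusted p = 0.302, blocked 0.0431; H1f5 -0.64).

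Other ovarian lists did not pass. Genes of ovulation and cumulus expansion were higher for 16 of 25 (median 0.13, adjusted p = 0.221), with the EGF-like factors Ereg at 1.03 and Btc at 0.40 and the cytokine Il6 at 0.80. Without the control pool this list passed (adjusted p = 0.00177; adjusted p = 0.962 with all arrays and an estimated correlation), as did cell cycle genes (0.0422; adjusted p = 0.995). With all arrays the cell cycle genes were lower for 13 of 23 (median -0.06). Their median was -0.31 between the high mice, 0.30 between the low mice and -0.02 between the pools. Steroid-synthesis genes were higher for 10 of 14 (median 0.10, adjusted p = 0.321; Sult1e1 0.48, Hsd17b1 -0.48). Corpus luteum genes were higher for 11 of 16 (median 0.08, adjusted p = 0.302; Cyp11b1 0.42). Oocyte genes were higher for 14 of 28 (median -0.01, adjusted p = 0.988; Nlrp14 0.61, Gja4 -0.51). Ribosomal protein genes were lower for 17 of 21 (median -0.17, adjusted p = 0.321; Rps15 -0.65), and glucocorticoid-induced genes were higher for 13 of 24 (median 0.01, adjusted p = 0.988; Zbtb16 0.52). Among inflammatory genes Il1b differed by 0.53 and Ccl4 by -0.43 (adjusted p = 0.988). Median, mean and test differed in sign for the oocyte, surface epithelium, adipose, glucocorticoid, immediate early, inflammatory and cell cycle lists. With an estimated correlation no list call held in any of the 3 tissues.

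A further question was how mice with many and few ovulated oocytes differed. In hypothalamus, Atp5e, a subunit of ATP synthase, was 1.11 ± 0.17 (SE) higher in high than low mice, and the membrane protein gene Tmem256 1.10 ± 0.18 (SE) higher. Cdr1 was -1.93 ± 0.25 (SE) and Ankrd49 -1.47 ± 0.18 (SE), with the same direction in the control and the stressed pair, which the naming rule required. In ovary, the cell cycle regulator Cks2 was 1.24 ± 0.17 (SE) higher in high mice, neurotensin (Nts) 1.17 ± 0.17 (SE) and the endotoxin co-receptor Ly96 1.15 ± 0.17 (SE), while Palld was -1.16 ± 0.15 (SE) and the imprinted gene Peg3 -1.10 ± 0.17 (SE). In pituitary, the kallikreins Klk1b27 and Klk1b24 were 1.95 ± 0.27 (SE) and 1.73 ± 0.41 (SE) higher, and Sox18, an endothelial transcription factor, was -1.07 ± 0.23 (SE). None of these genes passed the threshold, and each class held 2 mice.

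The limma counts for high against low mice were 0, 0 and 0 in hypothalamus, pituitary and ovary, with 4275, 1160 and 2382 genes at an unadjusted p under 0.05. The lowest adjusted p was 0.135, 0.900 and 0.408. In hypothalamus the count rose to 215 genes (22 higher, 193 lower) with all 18 arrays in a single model, to 955 (216 higher, 739 lower) with a trended robust prior and to 1138 (274 higher, 864 lower) among genes at or above the median level. In ovary it was 6 with a trended robust prior and 27 without the control high mouse. In simulated data this test made 30 false calls among 161 in hypothalamus, 19 among 119 in pituitary and 20 among 142 in ovary, more than the threshold of 0.05 allows. Across genes, the high minus low differences of control mice and of stressed mice correlated at 0.324 in hypothalamus, 0.0543 in pituitary and 0.124 in ovary. The other genes filled in were S100a13, Rprl2 (1.02), Cd209a, Zfp942, Xkr4 and Zfp518a (-1.42) in hypothalamus, Bmi1 (1.16), Vaultrc5, Snhg17, Ap5b1, Ceacam2 (-1.29), Fmod and Aff2 in pituitary, and H2bc12 (1.22), Omd, Sh3pxd2b, Plxna4 and Fam20a (-0.92) in ovary.

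Gene lists were tested for high against low mice after the data had been seen. In hypothalamus, ribosomal protein genes were higher in high mice for 17 of 21 (median 0.50, limma camera adjusted p = 0.000209) and immediate early genes for 19 of 22 (median 0.40, adjusted p = 0.000402). With an estimated correlation these were adjusted p = 0.907 and adjusted p = 0.912. In pituitary, endothelial and mural cell genes fell (median -0.41, adjusted p = 0.000117, and adjusted p = 0.601 with an estimated correlation), as did circadian clock genes (median -0.17, adjusted p = 0.0139, and adjusted p = 0.601 with an estimated correlation) and cell cycle genes (median -0.29, adjusted p = 0.00682, and adjusted p = 0.649 with an estimated correlation). The cell cycle median was -0.07 in control mice and -0.48 in stressed mice. Interferon genes were higher in high mice of pituitary (median 0.80, adjusted p = 8.34e-08, and adjusted p = 0.601 with an estimated correlation) and ovary (median 0.89, adjusted p = 9.35e-06, and adjusted p = 0.806 with an estimated correlation). Their high minus low medians were 1.79 and 1.75 in stressed mice but 0.04 and -0.05 in control mice. Adjusted over the list alone, 8 ribosomal protein, 5 interferon, 3 oligodendrocyte and 2 astrocyte genes passed in hypothalamus, with 1 each of the reproductive, lymphocyte, apoptosis, circadian and histone lists. In pituitary 1 interferon gene did, and in ovary 4 macrophage, 3 theca and stroma, 2 steroid-synthesis, 2 ovulation, 1 adipose and 1 histone gene, while over all genes 0 did. The high minus low difference fell with genomic span over protein-coding genes at or above the median level. Spearman rho across genes was -0.376 in hypothalamus, -0.206 in pituitary and -0.268 in ovary. Histone genes had a median of 0.39 in hypothalamus (limma camera adjusted p = 0.235).

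The last question was whether the stress difference of a gene varied between tissues. Ccn5, a matricellular protein, differed by 0.77 under stress in pituitary and by -0.47 in ovary. In pituitary it differed by 1.30 between the pools and by 0.49 and 0.51 between the high and the low mice. It read 9.24 to 10.23 in ovary, and the stressed pituitary pool held ovarian transcripts. Thbs4 likewise read 5.72 in that pool, 3.84 in the control pool and 7.80 to 9.15 in ovary. Rnase2a, a ribonuclease of eosinophils, differed by 2.02 in ovary, where it read 7.52 in the stressed high mouse and 5.41 and 5.54 in the other stressed samples, and by 0.20 in hypothalamus. Its ovary minus hypothalamus difference was 1.82, and 1.24 without the stressed high mouse. The DNA damage kinase Chek2 differed by -0.76 in pituitary and 0.30 in ovary. The other genes named, in order of unadjusted p since most adjusted p values were tied, were Ifna16, Stfa1, Hnf4g, Slc10a6 and Tceal7 for pituitary against hypothalamus, Cyp4a12b, Ibsp, Phf11d and Ildr2 for ovary against hypothalamus, and Mmel1 and Hnf4g for ovary against pituitary. Ifna16, Stfa1, Hnf4g and Tceal7 averaged 1.73, 3.10, 3.19 and 3.05 over all arrays, below the 25th percentile of each array (3.29 to 3.69). Interaction tests in limma with the animal as a block gave 0 genes for each pair of tissues, with 837, 558 and 846 genes at an unadjusted p under 0.05. Without a block the counts were 0, with 373, 247 and 418 genes under that level, and the lowest adjusted p with the block was 0.969, 1 and 0.9998.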

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

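The tests of list differences between tissues were added after the data had been seen. So were the tests of leukocytes and of an array-wide shift, which were chosen only after the interferon values were known, and the splits with an estimated correlation.

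For 18 lists measured in all 3 tissues, the stress difference was compared between tissues with limma camera on the interaction (adjusted over 54 tests). Interferon genes differed by a median of 0.24 between pituitary and hypothalamus (adjusted p = 0.0341) and by 0.43 between ovary and hypothalamus (adjusted p = 1.35e-05). Their stress medians in pituitary and ovary were 1.53 and 1.77 between the high mice, and -0.20 to 0.03 in the other classes. These interferon differences thus rested on the stressed high mouse. Cell cycle genes differed by -0.41 between pituitary and hypothalamus (adjusted p = 5.27e-05) and by 0.35 between ovary and pituitary (adjusted p = 0.00323). Their stress median in pituitary was -0.70 between the high mice and -0.54 between the low mice, but 0.26 between the pools. Ribosomal protein genes differed by -0.22 between pituitary and hypothalamus (adjusted p = 0.0341) and by -0.22 between ovary and hypothalamus (adjusted p = 0.0201). Immediate early genes differed by -0.12 between ovary and pituitary (adjusted p = 0.0341). With an estimated correlation none of these passed (adjusted p = 0.964 to 0.990).

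Interferon-induced genes were high in the stressed mouse with the most oocytes, with a median excess over the other 5 arrays of 1.61 in pituitary, 1.70 in ovary and 0.37 in hypothalamus. A rise of leukocytes as a whole was argued against in pituitary and ovary, where 33 macrophage and leukocyte markers had medians of -0.0953 and -0.0453 (SD 0.40 and 0.44), but stayed open in hypothalamus (0.175, SD 0.39). A median over mixed markers cannot exclude a rise of a single cell type. In that mouse's ovary Rnase2a read 7.52 (3.87 to 5.54 on the other ovary arrays) and the myeloid gene Ms4a6d 7.41 (5.63 to 6.82). The macrophage markers had a median of -0.19 there. For an array-wide shift, the ovary array of that mouse had a median signal of 4.87, against 4.78 to 4.84 on the other ovary arrays. These medians argue against a shift of this size in ovary. With medians this close, quantile normalization could hardly remove the excess (1.76 afterwards), so that step added little. A state of that animal, such as an infection or an interferon response to the transport in this mouse alone, may account for the values and could not be tested with 1 mouse of its kind.

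Cell cycle genes were low in the pituitary of stressed single mice, with 22 of 23 lower on average over the high and low pairs (median -0.67), and higher in the stressed pool for 18 of 23. A trend with gene span was argued against as the whole cause, since the median was -0.57 after the trend with span and level was removed (interquartile range -0.83 to -0.45). Ovarian RNA in the stressed pool could account for the opposite pool value, as all 23 genes were higher in ovary than in pituitary, but the pool difference did not follow the ovarian excess across genes (Spearman rho 0.00692), and with 23 genes this stayed undecided. Fewer dividing pituitary cells under stress and a difference in RNA quality remain untested explanations.

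For each tissue 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05. In the test of genes, the real split gave 0 in hypothalamus, pituitary and ovary and the highest other split 2, 0 and 0. In the test of lists the real split gave 1, 3 and 1 and the highest other split 4, 6 and 9, and 10, 6 and 10 of the 10 splits gave as many. With an estimated correlation the real and the highest other split gave 0 lists in each tissue. The higher counts of other splits may come from a structure of the samples other than treatment or from correlation within lists above the preset 0.01, which was not separated. Among the 4 splits that part all class pairs, the real one included, the highest other list counts were 3, 6 and 6. For the interactions the real split of the 6 animals gave 0, 0 and 0 and the highest other split 2, 1 and 0. A count of 0 is matched by any split, so the splits say nothing about these gene counts.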

How the results depend on the processing

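Leaving out the pool arrays and combining the class block with an estimated correlation were chosen after the data had been seen; the other alternatives were planned. The stress and interaction counts stayed at 0 genes under each alternative with an adjusted p. At an unadjusted p under 0.05 and at least 1.5-fold, stress gave 111, 216 and 216 genes in hypothalamus, pituitary and ovary, and at least 2-fold 4, 18 and 21. Interactions gave 683, 450 and 710 genes at that unadjusted p and 1.5-fold. The cause of the shifts below was not tested unless stated.

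High against low in hypothalamus moved from 0 to 215 genes with all 18 arrays in a single model, 955 with a trended robust prior, 1138 with fewer genes tested (those at or above the median level) and 2130 at an unadjusted p and 1.5-fold; leaving out an array gave 0 to 1, the 1 without the control high mouse. In pituitary it moved to 905 at an unadjusted p and 1.5-fold. In ovary it moved to 6 with a trended robust prior and 886 at an unadjusted p and 1.5-fold; leaving out an array gave 0 to 27, with 27 without the control high mouse and 1 without the stressed low mouse. Where this leaves a class with 1 array, that array is assumed to vary like the others.

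The number of lists (1, 3 and 1) was 0 in every tissue with an estimated correlation, with fry, and with an estimated correlation and the block. The block gave 5 in hypothalamus and 3 in ovary and changed no other call of the report. Hypothalamus gave 3 among genes at or above the median level and 2 without the pool arrays, and pituitary 6 without the pool arrays. Leaving out an array gave 0 to 5 lists in hypothalamus (0 without the control low mouse, 5 without the control pool), 1 to 4 in pituitary (1 without the control low or the stressed high mouse) and 1 to 4 in ovary (4 without the control pool). Interferon genes in pituitary had adjusted p values of 7.43e-10 to 0.114 when an array was left out, and without the stressed high mouse, at 0.114, they pointed down.

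Named genes kept their sign in 481 of 493 values in hypothalamus, 591 of 610 in pituitary and 482 of 495 in ovary, and in each value for high against low and for interactions. Genes filled in for stress and for high against low had groups without overlap, so leaving out an array could not turn their sign. Each sign change fell on the fixed reproductive and stress genes. These were Gnrh1, Kiss1, Crh and Npvf in hypothalamus, Fshb, Lhb, Cga, Gnrhr and Prl in pituitary, and Cyp11a1, Amh and Fshr in ovary. No background or detection values were used here, so signal over background was not assessed.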

Other observations

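The comparisons of pool with single-mouse arrays and the tests of a wrong tissue, of the signal distribution and of hypothalamic RNA were chosen after the data had been seen.

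Pool and single-mouse arrays differed widely. In limma, 1901 genes passed between pools and single mice in hypothalamus (1236 higher in pools), 4226 in pituitary (2611 higher) and 2327 in ovary (1584 higher). The pool differences correlated between tissues at 0.624 to 0.714 across genes, and pools had a wider spread of signals (SD 2.31 to 2.36) than single mice (2.15 to 2.28), so the values below need not reflect the tissues. The oocyte gene Zp3 read 9.39 in both ovary pools and 6.56 to 7.46 in single mice, and the granulosa gene Inha 12.47 and 12.49 against 11.29 to 11.72. Avp, the vasopressin gene, read 11.16 and 11.18 in the hypothalamus pools and 11.67 to 12.08 in single mice. Across single mice the synaptic gene Rph3a ranged from 4.90 to 9.66 in hypothalamus.

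Several cell type lists bear on what the dissections held. In hypothalamus, choroid plexus genes had a median of -0.01 under stress (adjusted p = 0.795), astrocyte genes -0.08 (0.685), and lymphocyte and neutrophil genes 0.06 (0.536). In pituitary, posterior lobe genes were lower for 8 of 12 (median -0.16, adjusted p = 0.613; Oxt -0.47) and corticotrope and melanotrope genes for 8 of 10 (median -0.11, adjusted p = 0.546; Pax7 -0.39). In ovary, theca and stroma genes were higher for 10 of 15 (median 0.13, adjusted p = 0.302; Ogn 0.75, Dcn 0.42). These were limma camera tests and none passed. Among 16010 clusters without an annotation, limma passed 0 in each tissue, with 418, 516 and 520 at an unadjusted p under 0.05.

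Transcripts of another tissue stood in the pool arrays, as with Prl at 11.44 in the stressed ovary pool and Cyp11a1 at 11.34 in the stressed pituitary pool. RNA or tissue carried over between samples is a candidate source: the excess of ovary-specific genes rose with their ovarian level in the stressed pituitary pool (Spearman rho 0.615 across genes) and the stressed hypothalamus pool (0.573), and that of pituitary-specific genes with their pituitary level in the control and stressed ovary pools (0.697 and 0.723). For hypothalamus-specific genes in the control and stressed pituitary pools this correlation was 0.294 and 0.236, between the bounds set, so their source stayed open. Such a correlation alone did not mark an excess. For pituitary-specific genes in the control hypothalamus pool it was 0.345, although their median excess was -0.01. In the other sets without an excess it ran from -0.153 to 0.089. The signal distribution of pools was argued against for the ovarian genes, with a median excess of 0.0267 in the control pituitary pool, and a wrong tissue label by the lower correlation of the stressed pituitary pool with ovary than with pituitary arrays of single mice (difference -0.0466). How such transcripts came into the pools could not be told from these values, and no biological explanation was tested.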
